A study of Escherichia coli BL21(DE3) with 6 samples.

How the data were processed

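Total RNA from 6 fermentation samples of Escherichia coli BL21(DE3) was depleted of ribosomal RNA and made into strand-specific Illumina libraries, per the labels' protocols. The submitters' processing notes name FastQC, cutadapt, Bowtie and Bowtie2 without versions or roles. The counting tool, genome build and annotation release were not given in the sources used here. For each hour the authors deposited a normalised expression signal per gene for the aerobic and the microaerobic library, the read count divided by a DESeq size factor set within that hour, per the deposited summary sheet and the values. The deposited sheets also hold the authors' fold ratio, its log2 value, a p-value and an adjusted p-value per gene from DESeq on 1 library against 1 library, per the file headers. All sheets of an hour were joined, giving 4399 genes, of which 4278 were listed at every hour. A gene not listed at an hour was taken as 0 in both of its libraries.

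The tests, the gene lists, the rule for named genes and the first group of alternatives below were fixed before the data were examined. That design assumed read counts first and limma for normalised values, and the values being normalised, limma was used. Every value above 0 was a whole multiple of the smallest value of its library (100% within a tolerance of 1e-04 reads), so whole reads were recovered. Totals ranged from 4966001 to 10288917 reads per library. Reads without molecular identifiers are not independent molecules, so the 95% counting intervals (exact Clopper-Pearson on the microaerobic share of a gene's reads at an hour) cover counting error only. At low depth they are wide: for malK at 12 h, with 3 microaerobic reads, the interval of the log2 ratio ran from -10.55 to -6.72.

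Genes were named by the deposited symbol (168), by a table of product descriptions written by hand for this work (509), or by a protein name in the annotation and the homology description (696), the annotation alone (161) or the homology description alone (1048). In all 2582 genes had a name, and 83 names that fell on more than 1 gene were taken back. Synonyms came from a gene table of another E. coli strain, with which 0 of the deposited locus tags matched, so no coordinates are given. Of 830 distinct symbols in 37 gene lists 727 were matched, and the 36 lists with at least 3 measured members were tested. The list of prophage genes had fewer. Which lists are described beyond the lactose and galactose ones was decided after the list tests were seen.

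The main test of oxygen was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend) on log2(value + 1) with the hour as a factor, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes entered with a mean over the 6 libraries of at least 10, which left 3837. Fold changes on this scale understate the change of low genes. The hours of one condition are not known to be separate cultures, so p-values measure only the spread between these samples. Gene lists were tested with camera on the same fit with a preset correlation of 0.01, beside an estimated correlation and fry. With so few residual degrees of freedom the estimated correlation had little power, so a miss by it does not alone count against a list. In the oxygen fit the estimate was 0.924 for ribosomal proteins, 0.897 for purine and 0.322 for methionine and cysteine biosynthesis, and -0.048 for the galactose list. The preset 0.01 lies far below the first 3, so camera p-values of lists whose genes move together may be much too small. The change of the oxygen effect with time was the coefficient of oxygen by hour, with 1 residual degree of freedom. For 14 h against 10 h the recovered reads were put on one scale by TMM library sizes (edgeR 4.0.16), since the deposited values were scaled within each hour, and 3828 genes entered. For single hours no test was made: genes with a mean of at least 10 over both libraries were counted at a 2-fold difference, and list medians were placed among 10000 random lists matched on mean expression in 10 bins (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, with matplotlib 3.10.9 for figures).

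The first group of alternatives was median-of-ratios size factors, limma without the trend, no filter, a minimum mean of 50, a pseudocount of 8, no hour in the model, each hour left out, oxygen left out of the model of 14 h against 10 h, an estimated list correlation and, for single hours, the same pseudocount and minimum, no minimum and a recentred median. Added after seeing the data were edgeR's quasi-likelihood test on the recovered reads, list members named without product descriptions, an estimated list correlation with each hour left out, a contrast of 10 h with 12 h and 14 h, and edgeR on 12 h and 14 h alone. Genes were named by a fixed rule: all measured members of the lactose and galactose lists, then the 10 largest called changes each way among genes with a symbol that moved the same way at all 3 hours, filled where fewer passed by genes at least 2-fold changed the same way at all 3 hours, leaving out multi-copy families. In each list described, up to 4 called members were named or, with none called, the 2 with the largest values. For time and its interaction with oxygen the rule takes 5 called genes each way. For the fit of 12 h and 14 h genes were taken, after the values were seen, from the 10 largest called changes each way and the 3 largest called members per list.

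The fits of oxygen, its interaction with time, 14 h against 10 h, 12 h and 14 h alone, and 10 h against later hours were tested on simulated data, once per dispersion, with independent reads drawn for the real genes at the real depths and 200 genes changed. At the dispersion estimated from the 6 libraries (0.183) the oxygen test by limma on 3800 genes recovered 65.7% of 4-fold and 8.16% of 2-fold changes, and edgeR 56.6% and 6.12%. For the interaction, on 3826 genes, limma recovered 27.0% of genes whose difference between conditions changed 4-fold every 2 h and 2.02% of those with a 2-fold change. For 14 h against 10 h, on 3812 genes, it recovered 30.6% of 4-fold and 1.02% of 2-fold changes. At the dispersion of the 12 h and 14 h libraries (0.0652), limma on 3822 genes recovered 86.7% of 4-fold and 23.2% of 2-fold changes with 11 false calls, and edgeR 80.6% and 19.2% with 3. For 10 h against later hours, at a dispersion of 0.0636 on 3812 genes, limma recovered 25.8% of 4-fold and 2% of 2-fold changes with 1 false call, and edgeR 18.6% and 2% with 0.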

Results

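RNA was sequenced from Escherichia coli BL21(DE3), a laboratory strain that carries the DE3 prophage, on which a lac-controlled gene for a phage RNA polymerase drives recombinant genes. Cells were grown to late log phase on lactose in an oxygen-controlled bioreactor, in an aerobic or a microaerobic fermentation, and sampled at 10, 12 and 14 h. The 6 libraries comprised 1 per condition and hour, so 3 per condition. The question named by the submitters was how microaerobic growth alters lactose metabolism. Read totals recovered from the deposited values were 5144599, 7728008 and 10288917 in the aerobic libraries of 10, 12 and 14 h. They were 9226704, 4966001 and 7426460 in the microaerobic libraries of the same hours. A single transcript, ssrA, the transfer-messenger RNA that rescues stalled ribosomes, took 17.4%, 10.6% and 9.60% of the aerobic reads and 18.4%, 27.7% and 15.3% of the microaerobic reads at 10, 12 and 14 h.

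The libraries did not group by their oxygen label at 10 h. Across 3828 genes on a common scale, the library labelled microaerobic at 10 h correlated with the aerobic libraries of 12 h and 14 h at Pearson r = 0.981 and 0.978, and with the microaerobic libraries of the same hours at 0.937 and 0.937. The library labelled aerobic at 10 h correlated with the microaerobic libraries of 12 h and 14 h at 0.95 and 0.941, and with the aerobic ones at 0.938 and 0.940. These are correlations across genes, and genes are not independent replicates. Principal component 1 held 46.6% of the variance. The aerobic libraries of 12 h and 14 h lay at -26.4 and -25.6 on it, and the library labelled microaerobic at 10 h at -19.4. The microaerobic libraries of 12 h and 14 h lay at 27.4 and 26.4, and the library labelled aerobic at 10 h at 17.6.

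**Figure D1:**
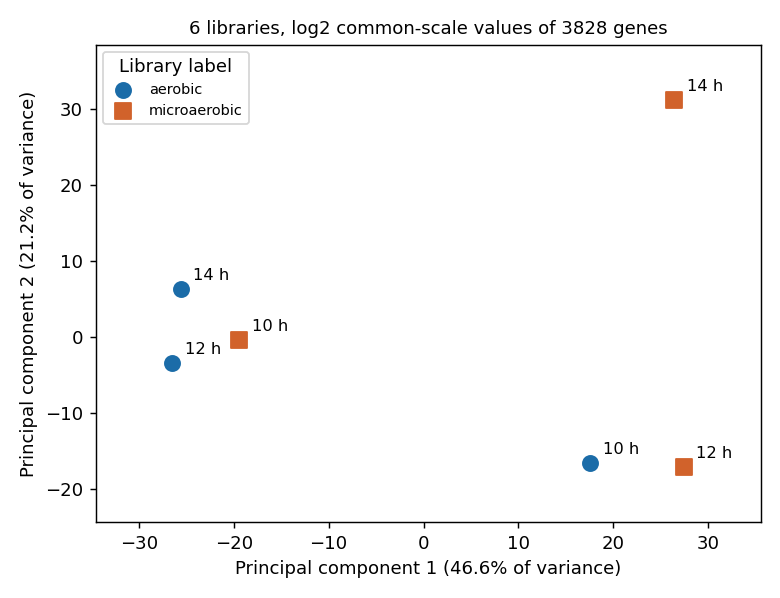
Position of each of the 6 libraries on principal components 1 (horizontal, 46.6% of variance) and 2 (vertical, 21.2%) of log2 common-scale values of 3828 genes, with circles for aerobic and squares for microaerobic libraries. The square of 10 h lies at -19.4 on component 1, on the side of the aerobic circles of 12 h and 14 h at -26.4 and -25.6.

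The first comparison asked which genes differed between microaerobic and aerobic cells over all 3 hours. Genes of lactose use had lower values in the microaerobic libraries at 12 h and 14 h but not at 10 h. For lacZ, the beta-galactosidase that splits lactose, the log2 difference between microaerobic and aerobic libraries was 0.63, -2.63 and -0.94 at 10, 12 and 14 h. For the lactose permease gene lacY it was 0.18, -2.77 and -0.89, and for the transacetylase gene lacA 0.27, -1.28 and -0.85. The repressor gene lacI (gene777) went the other way, at -1.09, 1.22 and 1.68. In the deposited numbering it stands near gene780 (ECD_RS03710, described as a DNA-dependent RNA polymerase) and away from lacZ (gene330). It may therefore not be the copy beside the lactose operon. A second gene with the symbol lacI (gene332) had at most 8 reads in any library, and the division of reads between genes that share a symbol is uncertain. Averaged over the hours, lacZ differed by -0.98 ± 0.69 (moderated SE, n = 3 libraries per condition, 1 per hour), lacY by -1.16 ± 0.60, lacA by -0.62 ± 0.40 and lacI by 0.60 ± 0.60. Each SE here and below is limma's moderated one, from a variance shrunk towards that of other genes, and not the plain SE of a gene's own values. The lactose list had a median of -0.80 (camera, adjusted p = 0.177; adjusted p = 0.794 with an estimated correlation), with 0 of 4 members past the threshold over all genes tested and 0 when adjusted over the list alone. Its median was -1.42 without the 10 h libraries (adjusted p = 0.258) and -0.22 without the 12 h libraries (adjusted p = 0.762). Without the 14 h libraries it was -0.75 (adjusted p = 0.0362, and adjusted p = 0.890 with an estimated correlation).

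Galactose outside the cell enters through the products of galP and the mgl operon. All 5 measured members of the galactose list had a negative mean log2 difference: galP -1.42 ± 0.66 (SE), galS -1.23 ± 0.37, mglA -1.14 ± 0.35, mglC -0.88 ± 0.30 and galR -0.17 ± 0.28. The list median was -1.14 (camera, adjusted p = 2.3e-04; adjusted p = 0.794 with an estimated correlation). Of these genes 0 passed over all genes tested, and 3 did when adjusted over the list alone. The methionine genes metB (2.0 ± 0.40), metF (1.97 ± 0.40) and metN (1.49 ± 0.30) were at least 2-fold higher at all 3 hours, as values. The glycine-cleavage gene gcvP (-1.73 ± 0.38), the aldehyde dehydrogenase gene aldA (-1.80 ± 0.36), the galactitol transporter gene gatB (-1.74 ± 0.44) and ygfF (-1.15 ± 0.30) were at least 2-fold lower at all 3. In all, 7 genes were at least 2-fold higher and 6 at least 2-fold lower at every hour, of which 3 and 4 had a symbol.

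Methionine and cysteine biosynthesis had the lowest p of the 36 gene lists tested. All 36 of its measured members had a positive mean difference, with a median of 0.93 (camera, adjusted p = 4.2e-16; adjusted p = 0.794 with an estimated correlation). Its median was 1.57 without the 10 h and 0.58 without the 14 h libraries. The sulfate-binding protein gene sbp (2.55 ± 1.40) and the regulator gene metR (2.25 ± 0.53) had the largest values. Over all genes tested 0 members passed, and 3 did when adjusted over the list alone. Purine biosynthesis had 14 of 14 members negative and a median of -1.71 (adjusted p = 5.1e-08; adjusted p = 0.794 with an estimated correlation), led by purM (-2.15 ± 0.78) and purT (-2.06 ± 0.74). Without the 14 h libraries its median was -0.60. The list of alternative carbon sources under the catabolite activator CRP had 47 of 54 members negative and a median of -0.47 (adjusted p = 7.5e-06; adjusted p = 0.794 with an estimated correlation). Its largest values were malK (-3.51 ± 1.70) and lamB (-2.56 ± 1.23), both of maltose uptake. In both lists 0 members passed over all genes tested and 0 when adjusted over the list alone. Without the 12 h libraries the carbon source list had a median of -0.16 and an adjusted p of 0.142, and without the 10 h libraries a median of -0.87.

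Other lists lay below the remaining genes, with 0 members past the threshold over all genes tested and 0 when adjusted over the list alone. Branched-chain amino acid biosynthesis had a median of -0.60 (camera, adjusted p = 0.00333; adjusted p = 0.794 with an estimated correlation), with ilvM at -1.96 ± 0.97 and ilvN at -1.28 ± 0.36. For arginine and pyrimidine biosynthesis the median was -0.55 (adjusted p = 0.0146; adjusted p = 0.849 with an estimated correlation), with argB at -1.04 ± 0.78 and pyrI at -0.97 ± 0.34. For histidine, tryptophan and threonine biosynthesis it was -0.36 (adjusted p = 0.0142; adjusted p = 0.849 with an estimated correlation), with hisH at -0.72 ± 0.32 and hisA at -0.53 ± 0.33. The galactitol and tagatose list had a median of -0.25 (adjusted p = 0.0278; adjusted p = 0.794 with an estimated correlation), with agaB at -1.88 ± 0.92 (1 microaerobic read against 33 at 14 h, 95% counting interval of the log2 ratio -9.99 to -2.06). The aerobic respiratory chain had 20 of 24 members negative and a median of -0.35 (adjusted p = 0.0254; adjusted p = 0.849 with an estimated correlation), with cydX at -1.18 ± 0.57 and cyoD at -0.90 ± 0.35. General stress genes under RpoS had a median of -0.33 (adjusted p = 0.00191; adjusted p = 0.794 with an estimated correlation), with ecnB at -1.30 ± 0.57 and csiD at -1.08 ± 1.06. Acetate assimilation had one of -0.73 (adjusted p = 0.0291; adjusted p = 0.794 with an estimated correlation), with acs at -0.95 ± 0.57 and yjcH at -0.73 ± 0.42. Without the 10 h libraries the calls of the galactitol (median -0.71, adjusted p = 0.0786), general stress (-0.24, 0.702) and acetate (-0.14, 0.704) lists ended, and the medians of the branched-chain (-1.14), arginine (-1.35), histidine (-0.73) and respiratory (-0.64) lists lay further from 0. Without the 12 h libraries the calls of the branched-chain (-0.25, 0.146), galactitol (-0.31, 0.254), histidine (-0.25, 0.275), arginine (0.028, 0.910) and respiratory (0.071, 0.514) lists ended, and the general stress median was -0.53. Without the 14 h libraries the calls of the histidine (-0.093, 0.946) and arginine (-0.29, 0.204) lists ended, and the galactitol and branched-chain medians were -0.58 and -0.37. The galactitol call also ended with median-of-ratios size factors (-0.18, 0.0755) and, without product descriptions as names, so did the galactitol (-0.094, 0.577) and histidine (-0.49, 0.0510) calls.

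Acid resistance lay above the other genes with a median of 0.37 (camera, adjusted p = 0.0142; adjusted p = 0.794 with an estimated correlation), with gadE at 1.37 ± 0.84 and cadB at 1.24 ± 0.64. Flagella and chemotaxis did too, with a median of 0.34 (adjusted p = 0.0280; adjusted p = 0.803 with an estimated correlation), although its largest single values were negative, cheB at -1.02 ± 0.63 (2 microaerobic reads against 23 at 12 h, counting interval of the log2 ratio -5.78 to -0.64) and cheY at -0.77 ± 0.67. Acid resistance lost its call without the 12 h (median 0.19, adjusted p = 0.275) or the 14 h libraries (0.14, 0.114), and flagella without the 10 h (0.13, 0.435) or the 14 h libraries (0.11, 0.440). The flagella call also ended with no filter (adjusted p = 0.0749) and without product descriptions as names (0.0613). The lists of fermentation, anaerobic respiration, the TCA cycle, heat shock and ribosomal proteins did not pass. Mixed-acid fermentation had a median of -0.17, a mean of -0.019 and a test direction above the other genes (adjusted p = 0.816), with adhE at -0.69 ± 0.67 (1.19, -1.87 and -1.40 at 10, 12 and 14 h, and -1.64 to -0.10 with an hour left out) and ackA at 0.58 ± 0.39. Without product descriptions its median was 0.35, and without the 10, 12 or 14 h libraries 0.15, -0.033 and -0.085. The anaerobic respiration list, which holds genes under the oxygen sensor FNR, had a median of 0.088 (adjusted p = 0.439), with torC at 1.13 ± 0.57 (1 aerobic read against 8 at 10 h, counting interval -0.51 to 7.86) and fdnI at 1.08 ± 0.50. Without the 10 h libraries that median was 0.019 (adjusted p = 0.704) and without product descriptions 0.13 (0.204). The TCA cycle list had a median of -0.18 (adjusted p = 0.282), with fumB at 0.81 ± 0.36 and sdhD at -0.76 ± 0.57. Without the 14 h libraries that median was -0.74 (adjusted p = 2.6e-06, and adjusted p = 0.890 with an estimated correlation), without the 12 h libraries -0.34 (0.537), without the 10 h libraries 0.35 (0.194) and without product descriptions -0.024 (0.626). Heat shock and protein folding had a median of 0.19 (adjusted p = 0.0885), with ibpB at 1.47 ± 0.83 and ibpA at 0.85 ± 0.63, and without product descriptions one of 0.32 (0.143). Ribosomal proteins had one of -0.11 (adjusted p = 0.494), with rpmD at -1.55 ± 0.95 and rpmG at -1.04 ± 0.84. Without the 12 h libraries it was 0.025 (adjusted p = 0.994). Without the 14 h libraries it was 0.49 (adjusted p = 2.5e-08, and adjusted p = 0.890 with an estimated correlation). Without the 10 h libraries it was -0.77 (adjusted p = 1.6e-07, and adjusted p = 0.837 with an estimated correlation), and the heat shock median was 0.50 (adjusted p = 0.0213, and adjusted p = 0.730 with an estimated correlation). In each list of this paragraph 0 members passed over all genes tested and 0 when adjusted over the list alone.

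Over all 3 hours, limma called 0 of 3837 genes higher and 0 lower in microaerobic cells at an adjusted p below 0.05, while 26 and 55 had an unadjusted p below 0.05. edgeR's quasi-likelihood test on the recovered reads also called 0 and 0, with 77 genes at an unadjusted p below 0.05. By camera with the preset correlation 13 of 36 lists passed, 3 above and 10 below the other genes, while 0 passed with an estimated correlation and 0 by fry. The hours differed in direction. Across the 3837 genes, which are not independent replicates, the log2 difference at 12 h correlated with that at 14 h at r = 0.59, while that at 10 h correlated with 12 h at -0.51 and with 14 h at -0.38. Without the 10 h libraries limma called 278 genes higher and 457 lower. edgeR on the same 4 libraries called 266 and 389, and 650 genes were called by both tools.

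**Figure D2:**
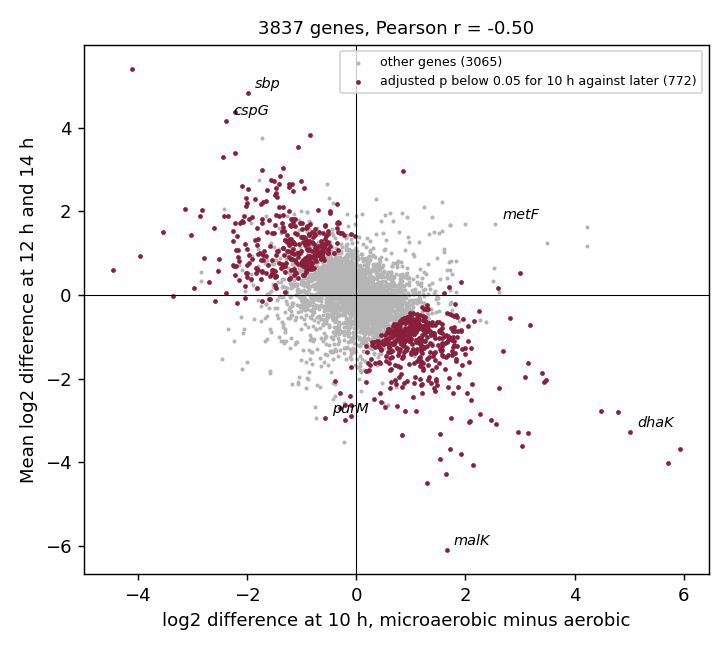
Each point is 1 of 3837 genes, with its log2 difference between microaerobic and aerobic libraries at 10 h (horizontal) and the mean of its differences at 12 h and 14 h (vertical). Dark points are the 772 genes whose difference at 10 h departed from that at 12 h and 14 h at a limma adjusted p below 0.05. That contrast was chosen after the 10 h libraries were seen to stand apart. It has 1 library per condition at 10 h and takes its spread from 12 h and 14 h. The correlation across genes was -0.50.

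At 12 h and 14 h alone, with 2 libraries per condition, the maltose genes malK, lamB, malE and malF, the lactose genes lacZ, lacY and lacA and 13 of 14 purine biosynthesis genes fell in microaerobic cells, while 26 of 36 methionine and cysteine genes rose. By camera with the preset correlation 16 of 36 lists passed, and 0 with an estimated one (lowest adjusted p = 0.730 with an estimated correlation). Leaving out each hour was planned, but this fit was set apart after the 10 h libraries were seen to run against the later ones. Without the 12 h or without the 14 h libraries limma called 0 genes higher and 0 lower. The adjusted p-values of this fit thus measure the agreement of 2 hours that were kept because they agreed. The genes named from this fit outside the lactose and galactose lists were chosen after their values were seen. Changes are log2 values ± SE with the limma adjusted p. The largest decreases among named genes were in maltose uptake: malK fell by 6.10 ± 0.50 (2.1e-08), the maltoporin gene lamB by 4.49 ± 0.33 (9.5e-09), malE by 4.28 ± 0.32 (9.5e-09) and malF by 3.80 ± 0.29 (9.5e-09). In the list of alternative carbon sources 26 of 54 members fell and 0 rose over all genes tested, and 30 fell when adjusted over the list alone. lacZ fell by 1.78 ± 0.39 (0.00273), lacY by 1.83 ± 0.35 (8.1e-04) and lacA by 1.07 ± 0.28 (0.0102). The lacI gene numbered away from them (gene777) rose by 1.45 ± 0.29 (0.00106), so 3 of 4 list members fell and 1 rose (3 and 1 adjusted over the list alone). The galactose transporter gene galP fell by 2.36 ± 0.30 (1.2e-05), mglA by 1.45 ± 0.30 (0.00182) and mglC by 1.04 ± 0.29 (0.0167), 3 of 5 list members (4 adjusted over the list alone). In the galactitol list 4 of 15 members fell and 1 rose (4 and 1 adjusted over the list alone), and gatB fell by 2.07 ± 0.36 (3.6e-04), gatA by 1.52 ± 0.34 (0.00345) and gatZ by 1.53 ± 0.38 (0.00634).

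In the same fit, 26 of 36 members of the methionine and cysteine list rose and 0 fell (29 rose when adjusted over the list alone). The gene sbp rose by 4.82 ± 0.29 (5.7e-10) (limma adjusted p in parentheses), the sulfonate-uptake gene ssuA by 3.53 ± 0.52 (5.6e-05) and metR by 2.95 ± 0.29 (4.2e-07). The regulator gene cbl, outside the list, rose by 3.30 ± 0.28 (3.2e-08). Of 14 purine biosynthesis members 13 fell (14 adjusted over the list alone), with purT at -2.98 ± 0.38 (1.0e-05), purM at -2.94 ± 0.44 (6.6e-05) and purL at -2.71 ± 0.42 (9.2e-05). Among arginine and pyrimidine genes 13 of 17 fell (14 adjusted over the list alone), including argC at -2.16 ± 0.30 (2.9e-05) and pyrB at -2.05 ± 0.35 (3.1e-04). Of 15 branched-chain genes 8 fell (8 adjusted over the list alone), led by ilvM at -3.36 ± 0.40 (3.8e-06) and ilvD at -2.03 ± 0.34 (2.1e-04). Of 16 histidine, tryptophan and threonine genes 4 fell (12 adjusted over the list alone), among them thrC at -1.12 ± 0.31 (0.0131) and thrB at -1.06 ± 0.29 (0.0124). Of 54 ribosomal protein genes 19 fell and 0 rose (28 fell when adjusted over the list alone), with rpmD at -2.77 ± 0.45 (1.6e-04) and rpmC at -2.34 ± 0.39 (2.3e-04).

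Genes of respiration, fermentation and stress split in this fit. In the aerobic respiratory chain 8 of 24 members fell and 1 rose (10 and 1 adjusted over the list alone), with cydX at -1.80 ± 0.51 (0.0176), nuoM at -1.44 ± 0.42 (0.0191) and nuoI at -1.42 ± 0.38 (0.0115) by limma. edgeR called 5 lower and 0 higher in this list, and did not call nuoM (adjusted p = 0.0627). The alcohol dehydrogenase gene adhE fell by 1.64 ± 0.31 (6.6e-04) and grcA by 1.04 ± 0.32 (0.0272), 2 of 14 mixed-acid fermentation members (2 adjusted over the list alone). Of 44 anaerobic respiration genes napA rose by 0.89 ± 0.29 (0.0351) while glpA fell by 1.14 ± 0.31 (0.0117) and nrdD by 1.02 ± 0.32 (0.0303), the last not called by edgeR (adjusted p = 0.0525), and 0 passed when adjusted over the list alone. In the TCA cycle list aceK alone passed, at 0.96 ± 0.30 (0.0299), and 0 when adjusted over the list alone. In acid resistance 3 of 13 rose (3 adjusted over the list alone): gadE by 2.66 ± 0.38 (4.0e-05), evgA by 1.81 ± 0.33 (4.9e-04) and gadX by 1.52 ± 0.36 (0.00474). Of 24 heat shock genes 5 rose and 2 fell (8 and 2 adjusted over the list alone), with the small chaperone genes ibpB at 2.71 ± 0.31 (3.0e-06) and ibpA at 1.70 ± 0.33 (8.6e-04), and cpxP at 1.71 ± 0.40 (0.00494). Among general stress genes osmC rose by 0.91 ± 0.29 (0.0336) and osmY fell by 1.30 ± 0.31 (0.00494), and 1 passed when adjusted over the list alone. In flagella and in acetate assimilation limma and edgeR both called 0 genes, with 4 and 0 at an unadjusted p below 0.05 by limma, and 0 passed when adjusted over the list alone.

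In the fit of 12 h and 14 h fry, which tests whether a list moves one way on balance without comparing it with other genes, passed 2 lists, the glucose phosphotransferase and the translation factor lists (adjusted p = 0.0255 for both). Among genes outside the described lists, the cold-shock gene cspG rose by 4.17 ± 0.41 (3.1e-07), the efflux gene mdtJ by 4.36 ± 0.64 (5.4e-05) (2 aerobic reads against 44 at 12 h, counting interval of the log2 ratio 3.39 to 8.42), the pyruvate transporter gene btsT by 3.83 ± 0.45 (3.8e-06) and iraD, whose product stabilises the stress sigma factor RpoS, by 3.39 ± 0.36 (9.0e-07), by limma. The genes yddB and yddA fell by 3.60 ± 0.28 (1.1e-08) and 3.30 ± 0.29 (6.8e-08). This fit had 1 residual degree of freedom per gene, so its spread rests on shrinkage across genes.

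**Figure D3:**
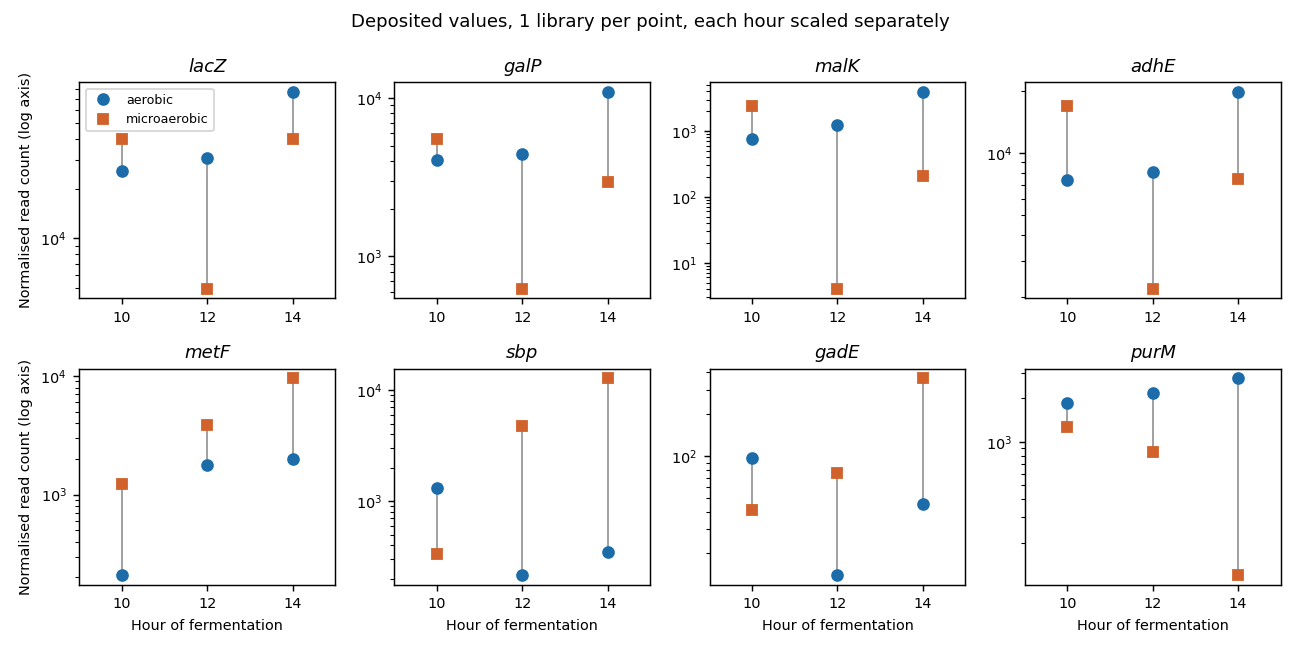
Deposited normalised read counts (vertical, log axis) of 8 genes at 10, 12 and 14 h (horizontal), with circles for aerobic and squares for microaerobic libraries, 1 library per point and no error bars. Each hour was scaled separately, so only the paired points of an hour compare directly: for metF the log2 difference was 2.54, 1.10 and 2.26, and for malK 1.65, -7.96 and -4.24.

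The second comparison took each hour alone, as the deposited tables do, with 1 library per condition, so these differences have no replicate check. The genes named for single hours were chosen after their values were seen. At 10 h, 353 of 3781 genes with a mean of at least 10 were at least 2-fold higher in the library labelled microaerobic and 385 at least 2-fold lower. The dihydroxyacetone kinase genes had log2 differences of 5.01 (dhaK), 4.79 (dhaL) and 4.49 (dhaM). Those of the ammonia-assimilation genes gdhA, gltD and gltB were 3.48, 3.44 and 3.40, and that of the methionine synthase gene metE was 3.18. On the lower side were csiD (-4.46), the fatty acid oxidation genes fadB (-2.78) and fadI (-2.42), the acetyl-CoA synthetase gene acs (-2.59) and cbl (-2.43). Ribosomal proteins had a median of 1.15, at percentile 100 of 10000 random lists matched on expression, with 37 of 54 at least 2-fold higher. Random lists hold genes drawn singly, so lists whose genes move together reach extreme percentiles more easily, here and below. Arginine and pyrimidine biosynthesis had a median of 1.20 (percentile 100). The TCA cycle had one of -1.03 and methionine and cysteine biosynthesis one of -0.57, both at percentile 0. In the latter list 9 genes were at least 2-fold higher and 12 at least 2-fold lower.

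At 12 h, 420 of 3719 genes were at least 2-fold higher in the microaerobic library and 464 at least 2-fold lower. The gene malK had 3 microaerobic reads against 1697 aerobic ones, a log2 difference of -7.96 (95% counting interval of the ratio -10.55 to -6.72). Among genes with a symbol it was followed by lamB (-5.30), malE (-5.03), dhaK (-4.46) and malQ (-4.13), and the tyrosine transporter gene tyrP stood at -3.89. On the higher side were btsT (5.44), sbp (4.44), ssuA (3.78) and cbl (3.36). The lactose operon had a median of -1.96 (percentile 0.19 of the random lists), the aerobic respiratory chain one of -1.16 (percentile 0) and alternative carbon sources one of -1.06 (percentile 0). Methionine and cysteine genes stood at 1.5 (percentile 100).

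At 14 h, 420 of 3901 genes were at least 2-fold higher in the microaerobic library and 490 at least 2-fold lower. Purine biosynthesis had a median of -3.57 (percentile 0 of the random lists), with 13 of 14 members at least 2-fold lower, among them purM (-4.51), purH (-4.29), purT (-4.15) and purE (-4.14). The xanthine permease gene xanP, outside the list, stood at -4.15. Ribosomal proteins had a median of -1.17 (percentile 0) with 33 of 54 at least 2-fold lower. On the higher side were cspG (5.24), sbp (5.19), iraD (3.99), the phage shock gene pspG (3.44) and metR (3.37). The oxidase genes cydA and cydB stood at 1.54 and 1.46, and cydX of the same oxidase at -2.38 (8 microaerobic reads against 60, counting interval -3.78 to -1.44). The aerobic respiratory chain list had a median of -0.029 (percentile 73.7) and the TCA cycle list one of 0.64 (percentile 100). The gene ECD_RS03710, described as a DNA-dependent RNA polymerase, differed by 0.17, -0.29 and -0.13 at 10, 12 and 14 h. The authors' deposited table lists 7, 6 and 8 genes as higher and 5, 15 and 26 as lower at an adjusted p below 0.05 at 10, 12 and 14 h, from tests that compare the libraries of an hour and not the conditions.

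**Figure D4:**
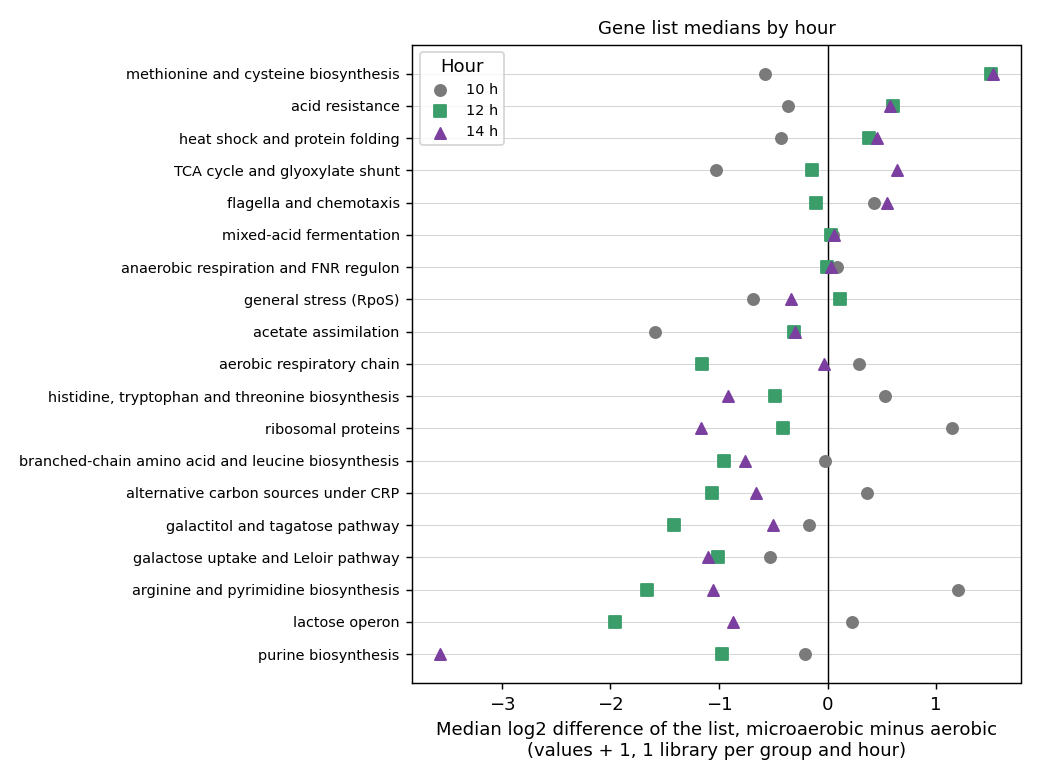
Median log2 difference, microaerobic minus aerobic (horizontal), of 19 gene lists (vertical) at 10 h (circles), 12 h (squares) and 14 h (triangles), from 1 library per condition and hour with no error bars. Methionine and cysteine biosynthesis lies at -0.57, 1.5 and 1.52, purine biosynthesis at -0.21, -0.97 and -3.57, and ribosomal proteins at 1.15, -0.41 and -1.17.

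The third comparison asked whether the difference between conditions grew or shrank in a straight line from 10 to 14 h. For purM the difference was -0.57, -1.37 and -4.51 at 10, 12 and 14 h, for ilvM 0.84, -2.22 and -4.49, and for rpmC 1.78, -1.10 and -3.59, genes chosen after their values were seen. At 14 h ilvM and rpmC had 22 and 54 microaerobic reads. Other genes of the branched-chain list did not keep falling, with ilvD at 1.32, -2.69 and -1.37 and ilvE at 1.33, -2.13 and -1.80. Ribosomal proteins had a median slope of -0.60 log2 units per hour (camera, adjusted p = 3.2e-23; adjusted p = 0.800 with an estimated correlation), and purine biosynthesis one of -0.85 (adjusted p = 4.4e-10; adjusted p = 0.800 with an estimated correlation). Methionine and cysteine genes had one of 0.51 (adjusted p = 1.1e-07; adjusted p = 0.800 with an estimated correlation), and TCA cycle genes one of 0.33 (adjusted p = 4.0e-06; adjusted p = 0.800 with an estimated correlation). Over all genes tested 0 members of these lists passed, and 12, 11, 4 and 7 did when adjusted over the list alone. limma called 0 of 3837 genes, with 352 at an unadjusted p below 0.05, and edgeR on the recovered reads called 0, with 337. By camera 15 of 36 lists passed, 0 with an estimated correlation and 0 by fry. These slopes take the 10 h labels as given, and an exchange of those labels would reverse each 10 h value. List medians at 10, 12 and 14 h were 1.15, -0.41 and -1.17 for ribosomal proteins and -1.03, -0.14 and 0.64 for TCA cycle genes, so both slopes rest on the 10 h sign. Purine biosynthesis, at -0.21, -0.97 and -3.57, depends on it less.

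The fourth comparison set 14 h against 10 h over both conditions on a common scale. The log2 differences of metF, metB and metR were 2.72, 2.41 and 2.41, and those of purM and sdhD -1.78 and -1.44, genes chosen after their values were seen. Histidine, tryptophan and threonine biosynthesis had a median of -0.36 (camera, adjusted p = 1.8e-05; adjusted p = 0.945 with an estimated correlation), and glycolysis one of 0.49 (adjusted p = 0.00671; adjusted p = 0.945 with an estimated correlation). Over all genes tested 0 members of both lists passed, and 5 and 0 did when adjusted over the list alone. limma called 0 of 3828 genes, with 88 at an unadjusted p below 0.05, and edgeR called 0, with 81. By camera 11 of 36 lists passed, 0 with an estimated correlation and 0 by fry. Among the 11 was the stable RNA list, set as a check of library composition. Its median was -1.06 with 4 of 4 members lower (camera, adjusted p = 0.0105, and adjusted p = 0.945 with an estimated correlation). A difference in library composition between 10 h and 14 h may thus bear on these values. The library labelled microaerobic at 10 h is among the 10 h libraries here. An exchange of the 10 h labels would change the spread of this fit but not its log2 differences.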

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

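The tests of 10 h against later hours, of labels, depth, scaling and read numbers, and the counts over other splits of the libraries were chosen only after the results were seen. When the microaerobic minus aerobic difference at 10 h was set against that at 12 h and 14 h, limma found 446 of 3837 genes whose difference was higher at 10 h and 326 whose difference was lower. edgeR's quasi-likelihood test on the recovered reads found 712 in all, of which 688 were called by both tools. At 10 h this contrast has 1 library per condition. Its 1 residual degree of freedom holds the spread between the 12 h and 14 h differences, so its calls carry no spread between libraries of 10 h. The contrast was also chosen because the 10 h pair stood apart, so its counts restate that observation. The largest values above, in log2 units, were those of dhaK (8.29), malK (7.75), dhaL (7.59), dhaM (7.27) and yddB (6.64) among genes with a symbol. Those below were sbp (-6.80), mdtJ (-6.57, with 3 microaerobic reads at 10 h), cspG (-6.55), cbl (-5.73) and iraD (-5.61). Both orders depend on the sign of the 10 h difference. At 10, 12 and 14 h the differences were 5.01, -4.46 and -2.10 for dhaK, 1.65, -7.96 and -4.24 for malK, and -1.99, 4.44 and 5.19 for sbp. Of the 735 genes called at 12 h and 14 h, 636 (86.5%) had the opposite sign at 10 h. The share over all genes tested was not counted, but across them the 10 h difference correlated with the mean of the later ones at -0.50. The opposition is thus not particular to the called genes. All values of this paragraph take the 10 h labels as given, and an exchange of those labels would reverse the sign of every 10 h difference and so of this opposition.

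A difference in depth, larger in the microaerobic library at 10 h and in the aerobic ones later, is argued against: with every library thinned to 4966001 reads, the correlation across genes of the 10 h difference with the mean of the later ones averaged -0.519 over 10 draws (-0.524 to -0.512; 3668 to 3679 genes), against -0.530 to -0.525 for the same genes before thinning. A wrong label on the library labelled microaerobic at 10 h stays open, since its mean correlation with the later aerobic libraries (0.979) exceeded that with the later microaerobic ones (0.937) by 0.0424, more than the gap inside either pair (0.00338). An exchange of both 10 h labels also needs the library labelled aerobic at 10 h out of place. Its margin towards the later microaerobic libraries was 0.00655, less than the gap inside a pair (0.00821). This margin cannot tell an exchange from a single wrong label. The same library correlated with the later aerobic libraries at 0.9378 and 0.9402, below the 0.9808 between those libraries. With the microaerobic libraries of 12 h and 14 h it correlated at 0.9496 and 0.9414, on either side of the 0.9453 between them. On principal component 1 it lay on their side, at 17.6. These values rest on 1 library, so neither reading is settled. An effect of oxygen that differed between 10 h and the later hours may give the same values, as may a difference in growth stage between the 10 h cultures, and neither was tested apart from the labels, because each condition has 1 library per hour.

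The purine biosynthesis genes, low in the microaerobic library of 14 h, were weighed as well. The scaling of the 14 h table is argued against, since a scaling factor moves all genes of a library alike. The median log2 difference of 3901 genes at that hour was -0.013, against -3.57 for the list. Size factors set within an hour hold the first value near 0, so it does not show that the factor was right. Only the gap between these values counts, which a common factor cannot make. The list median lay at percentile 0 of 10000 random lists of that hour matched on expression, but the list was picked for its low values, so this percentile restates the choice. Too few reads are argued against too, since 100% of the 14 members had a 95% counting interval below 0, with at least 31 reads in each library. An effect of oxygen or of something particular to that culture or library stays open and untested, with 1 library per condition at that hour.

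For the oxygen comparison over 3 hours the 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 genes, which 10 of 10 splits reach by necessity, so the count of genes decides nothing, and the highest of the others gave 390. For gene lists the real split gave 13, 6 of 10 splits gave as many, and the highest of the others gave 17. In 6 of the 10 splits both libraries of an hour fall on 1 side, so that with the hour in the model they rest on 1 pair of libraries, and of the 4 that keep 1 library of each hour on each side 2 gave as many lists, the real one included. The split with 390 genes puts the library labelled aerobic at 10 h with the microaerobic libraries of 12 h and 14 h, which points to a structure of the samples but restates the correlations given for the 10 h libraries and is no separate evidence.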

How the results depend on the processing

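Tests with edgeR, with list members named without product descriptions, with a correlation estimated while an hour was left out and with 10 h set against later hours were chosen only after the results were seen. The counts of 0 genes for oxygen, its straight-line change with time and 14 h against 10 h stayed 0 with limma without the trend, median-of-ratios size factors, no filter and edgeR, for oxygen also with a minimum of 50 and a pseudocount of 8, and for 14 h also without oxygen in the model. The libraries of an hour share their sampling time and scaling, and no label ties them to a common culture or batch. Their deviations from the group means correlated across genes at -0.468, -0.0883 and 0.0167 at 10, 12 and 14 h, and with no replicate block the oxygen counts were 0 and 0. Those group means include the 10 h libraries, which lay apart from their groups in opposite directions. The correlations thus restate that opposition in part and cannot show whether the libraries of an hour share a culture or batch. With hours left out in turn there were 0 to 278 genes higher, 0 to 457 lower and 6 to 16 lists, against 0, 0 and 13. edgeR on 12 h and 14 h alone gave 266 and 389 genes, and 10 h against later hours 772 (edgeR 712). With an estimated correlation 0 lists passed, also with each hour left out, but with so few residual degrees of freedom that test had little power. The preset correlation may in turn be too low for lists whose genes move together. With the preset correlation 5 passed without product descriptions, where lists had fewer members, against 13. At single hours a minimum of 50, with fewer genes tested, gave 255 lower at 10 h, 241 higher at 12 h and 249 higher at 14 h.

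With hours left out in turn, direction turned in the list medians of arginine and pyrimidine biosynthesis (-1.35 to 0.028), the aerobic respiratory chain (-0.64 to 0.071), the TCA cycle (-0.74 to 0.35) and ribosomal proteins (-0.77 to 0.49), in the test of mixed-acid fermentation (medians -0.085 to 0.15), and in the log2 values of aceK (-0.67 to 0.96), cpxP (-0.34 to 1.71), csiD (-1.93 to 0.60), dhaK (-3.28 to 1.45), dhaL (-2.80 to 1.49), dhaM (-2.78 to 1.35), evgA (-0.28 to 1.81), nuoI (-1.42 to 0.024), nuoM (-1.44 to 0.37), osmC (-0.17 to 0.91), rpmC (-2.34 to 0.34), rpmG (-2.09 to 0.18), sdhD (-1.32 to 0.055), thrB (-1.06 to 0.048), thrC (-1.12 to 0.23) and yddA (-3.30 to 0.020). The TCA cycle list also turned in test direction without product descriptions, at a median of -0.024. By edgeR aceK was at 0.045, and on 12 h and 14 h alone aceK was at 1.0, csiD at 0.64 and sdhD at 0.086. The cause was not tested. Depth limits genes with few reads, such as malK with 3 at 12 h.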

Other observations

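The lists and genes of this part were chosen only after their results were seen, and lists are given as medians of log2 differences at 10, 12 and 14 h with 1 library per condition and hour. Genes of envelope and phage shock stood at -1.45, 0.58 and 0.74 (percentiles 0, 99.47 and 99.93 of 10000 random lists), and in the limma fit of 12 h and 14 h 5 of 12 rose and 1 fell (5 and 1 adjusted over the list alone). ATP synthase genes stood at 1.45, -1.34 and -0.95 (percentiles 99.95, 0.06 and 2.29), and 8 of 9 fell in that fit (8 fell and 1 rose adjusted over the list alone), while edgeR called 5 lower. Iron uptake genes stood at 0.35, -0.19 and -0.49, with 7 of 43 lower and 0 higher in that fit (6 and 0 adjusted over the list alone, and 6 lower by edgeR). Iron-sulfur cluster assembly stood at 0.29, -0.022 and -1.30, the last at percentile 0.01.

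For the gene described as lysine-sensitive aspartokinase (ECD_RS20485) the log2 differences at 10, 12 and 14 h were 5.93, -4.84 and -2.54, and for the lysine permease (ECD_RS10820) 5.71, -4.65 and -3.39. For cyanate hydratase (ECD_RS01555) they were 2.07, -2.89 and -3.18. A hypothetical protein (ECD_RS25460), whose homology description is the leader peptide of iraD, stood at -4.11, 5.41 and 5.40.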
